A study of Mus musculus with 9 samples.

How the data were processed

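RNA was profiled in 9 samples of primary mouse microglia on Illumina bead arrays, in 3 groups of 3: unstimulated cells, cells given lipopolysaccharide (LPS) with interferon-gamma (IFNγ) for 16 h, and cells given interleukin-4 (IL-4) for 48 h. Per the labels' protocols, RNA was extracted with TRIzol and turned into biotin-labelled cRNA with a TargetAmp kit. IFNγ was given at 20 ng/ml and IL-4 at 100 U/ml. LPS is listed at 100 with a unit (n/ml) that is incomplete, so its dose is left open here. The labels give no culture time for the unstimulated cells. They do not say whether the replicates are separate cultures, so every p-value measures only the spread between these samples.

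The authors deposited 2 tables with 45281 probes each. The first holds the scanner's intensity per probe and array on a linear scale, with no background subtraction and no scaling between arrays, per the file headers and the values. Beside each intensity stands a detection p-value, also deposited by the authors, which ranks the probe against background. The second deposited table holds log2 values. Set against the intensities, these were quantile-normalized log2 signals to which a shift had been added per probe, equal and opposite on the 2 slides. Across probes the shift was 0.5 times the slide coefficient of a fit of group and slide, with a correlation of 1.00. The submitters' processing notes name Partek without its role or version. Slides were read from the array identifiers in the labels: slide 1 held IL-4 replicates 1 and 2 and LPS + IFNγ replicates 1 and 2, and slide 2 held the other arrays, among them all 3 unstimulated ones.

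All comparisons started from the intensities. Background was corrected with limma 3.58.1 in R 4.3.3 (normexp with negative-control parameters inferred from the detection p-values, offset 16), and the values were put on the log2 scale and quantile-normalized. A probe was kept when its detection p-value was under 0.05 on at least 3 of the 9 arrays, which left 16895 probes. Groups were compared in 1 linear model of the 3 groups with limma's moderated test (no covariate, no trend), with Benjamini-Hochberg adjustment within each of the 3 comparisons and a threshold of 0.05. A moderated F-test asked which probes differed among the 3 groups. No t-test was run on single genes outside limma. The labels state no statistical model, and these choices were made before the data were examined.

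Gene names came from the probe annotation supplied with the series' table: 34885 probes carry 1 symbol, 18 carry several and 10378 carry none, and 34807 of the first kind matched the reference gene table by gene number. Each of the 9391 genes measured is represented by its kept probe with the highest mean. Named genes follow a rule fixed in advance: in each comparison the 8 largest rises and the 8 largest falls among genes past the threshold whose 3 arrays of one group all lie beyond the 3 of the other and that were detected in both groups; up to 4 more per direction that were not above background in the lower group; the 4 members of each gene list with the lowest adjusted p, of which the text uses 2 to 4; and Cnr2 with the other endocannabinoid genes. Predicted genes and clone names were passed over. Where a gene was not detected on any array of the lower group, the change is given as a lower bound ("at least N-fold"), with each undetected value raised to the lowest detected normalized value of its array.

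The 26 gene lists were also fixed in advance: inflammatory cytokines and chemokines, interferon-stimulated antiviral genes, interferon-gamma GTPases and regulators, MHC class I antigen processing, MHC class II and costimulation, IL-4 response and alternative activation, homeostatic microglia genes, endocannabinoid system, Alzheimer-linked genes, scavenger, Fc and phagocytic receptors, complement system, nitric oxide, oxidative burst and antioxidant genes, Toll-like receptor and NF-kB signalling, cell cycle, glycolysis, cholesterol synthesis, oxidative phosphorylation, lysosomal genes, ribosomal proteins, housekeeping genes, and markers of astrocytes, the oligodendrocyte lineage, neurons, endothelial, mural and fibroblast cells, border macrophages, and lymphocytes and neutrophils. Of their 532 entries, 491 have a probe on the array under that symbol alone. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 75 tests (25 lists with at least 2 measured genes in 3 comparisons), and again with an estimated correlation. Lists overlap, and several markers of other brain cells are also expressed by macrophages.

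Whether equal replicate numbers pair the samples was checked with the correlation across probes of each array's deviation from its group mean. For IL-4 against unstimulated cells the pairs of equal number gave 0.366, 0.427 and 0.30, each the highest for its array. The deviations within a group are tied by its mean, so these are not separate results. With so few arrays, equal numbers could also match best without pairing. A value with replicate as a block therefore stands beside that result. For LPS + IFNγ against unstimulated cells the same correlations were -0.0053, -0.041 and -0.033. For LPS + IFNγ against IL-4 they were -0.12, -0.068 and 0.069. Those comparisons were therefore not treated as paired, and a replicate block there is an alternative only.

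The fit was tested on simulated data with the arrays' own spread, with 200 of 16895 probes changed in 10 simulations. A log2 change of 2 was recovered for 59.9% of the changed probes in LPS + IFNγ against unstimulated cells, 57.4% in IL-4 against unstimulated cells and 59.4% in LPS + IFNγ against IL-4. A log2 change of 1 was recovered for 0.90%, 0% and 0.55% in the same order. Of the calls at a change of 2, 20.6%, 0.252% and 19.8% were false in these simulations, above the nominal rate where the LPS + IFNγ group entered, whose replicate 2 has a weak signal. With that array left out, 86.4%, 90.2% and 85.0% were recovered at a change of 2, and 2.48%, 5.65% and 3.88% of the calls were false.

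Alternatives planned in advance covered background correction, a larger offset, cyclic loess and median centring, the deposited log2 table, filters on dim probes, slide and replicate blocks, each slide alone, each comparison's own 6 arrays, moderation with trend and robust, array quality weights, a 2-fold threshold, the mean over a gene's probes, the estimated correlation, and each array left out. Chosen after seeing the data were the fits that leave out LPS + IFNγ replicate 2 together with a slide block, a replicate block or IL-4 replicate 1, and the replicate block on the 6 IL-4 and unstimulated arrays. Figures were drawn with matplotlib 3.10.9.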

Results

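The arrays measured gene expression in primary microglia, the resident macrophages of the brain, cultured from the cortex of C57BL/6J pups aged 1 to 5 days with an intact cannabinoid receptor 2 gene (CB2+/+, gene Cnr2). The study's title concerns loss of this receptor in a mouse model of Alzheimer's disease. The arrays analysed here are all wild type, and they ask how microglia respond to LPS with IFNγ, a classical inflammatory stimulus, and to IL-4, a cytokine of alternative macrophage activation. Each of the 3 groups has 3 arrays, and this number limits the precision. On 8 arrays the mean intensity lay between 310.9 and 378.5 and between 14475 and 16435 of the 45281 probes were detected. LPS + IFNγ replicate 2 was weaker, with a mean intensity of 112 and 6208 detected probes. Its normalized values correlated across probes with those of replicates 1 and 3 at r = 0.765 and 0.761, against 0.980 between those 2 arrays (genes are not independent replicates). It was kept, and results are also given without it.

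**Figure D1:**
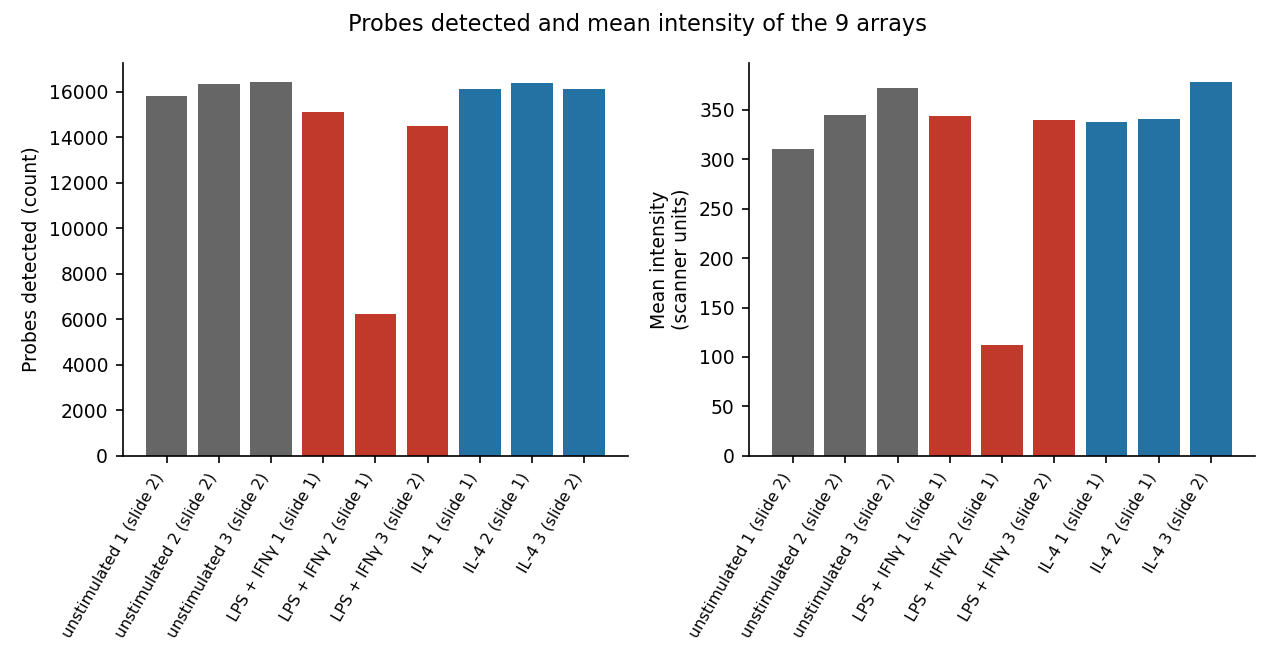
Bars give the number of detected probes (left) and the mean intensity in scanner units (right) of each of the 9 arrays, coloured by group, with the slide in brackets. LPS + IFNγ replicate 2 has 6208 detected probes, and the other arrays have between 14475 and 16435.

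LPS with IFNγ was compared with no stimulus to describe the inflammatory response. Among genes detected in both groups the largest rise was that of Cxcl9, an interferon-induced T cell chemokine, with a log2 difference of 9.80 ± 0.46 (SE, n = 3 arrays per group, adjusted p = 2.49e-05, limma). Cd40, a costimulatory receptor, rose by 7.20 ± 0.63, Lcn2, which binds bacterial siderophores, by 6.99 ± 0.56, and Cxcl10, another interferon-induced chemokine, by 6.84 ± 0.76 on the same scale. Gbp2 (an interferon-induced GTPase) rose by 6.92, Mmp13 (a collagenase) by 6.78, Traf1 (an adaptor of tumour necrosis factor receptors) by 6.6 and Slamf7 (an immune cell receptor) by 6.44. Without stimulus Cxcl9 and Traf1 were detected on 2 arrays and Lcn2 on 1. With undetected values raised in the same way as for bounds they rose by 9.75, 6.51 and 6.80. Among genes not above background in unstimulated cells, Upp1, a uridine phosphorylase, rose at least 87.3-fold, Serpina3f, a serine protease inhibitor, at least 86.1-fold, and the GTPases Gbp2b and Gbp5 at least 73.2-fold and 68.8-fold. All 3 arrays of one group lay beyond the 3 of the other for each of these genes and for the falls that follow.

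Cx3cr1, the fractalkine receptor of resting microglia, fell by 6.23 ± 0.74 (log2, SE, n = 3 arrays per group, adjusted p = 0.00114). It fell by 5.61 without LPS + IFNγ replicate 2, less than Mrc1, which then fell by 6.35. With all arrays Mrc1, the mannose receptor, fell by 6.19 ± 0.58, St6gal1, a sialyltransferase, fell by 6.06 ± 0.67, and Adssl1, an enzyme of purine nucleotide synthesis, fell by 5.84 ± 0.63. Rnase4 fell by 5.60, Olfml3, a secreted glycoprotein of microglia, fell by 5.57, Gas6, a ligand of the receptors that recognise dying cells, fell by 5.41, and Trf (transferrin) fell by 5.38. Of these 8 genes Gas6 was detected on all 3 LPS + IFNγ arrays, Mrc1 and Rnase4 on 1 and the others on 2, so part of each other fall is measured against background. With the undetected values raised to the lowest detected value of their array, Cx3cr1 fell by 5.23, Mrc1 fell by 5.25, St6gal1 fell by 5.15, Adssl1 fell by 5.26, Rnase4 fell by 4.58, Olfml3 fell by 4.59 and Trf fell by 4.53. Trf fell by 3.79 without LPS + IFNγ replicate 2, and with slide as a block its adjusted p was 0.106. Not above background after LPS + IFNγ were Hpgd, the prostaglandin-degrading dehydrogenase, at least 65.8-fold lower, Slco2b1, an organic anion transporter, at least 55.9-fold lower, Man2a2, a Golgi mannosidase, at least 19.6-fold lower, and Gpr183, an oxysterol receptor, at least 11.1-fold lower. For Man2a2, 3 other probes did not pass the test and 1 of them pointed the other way.

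**Figure D2:**
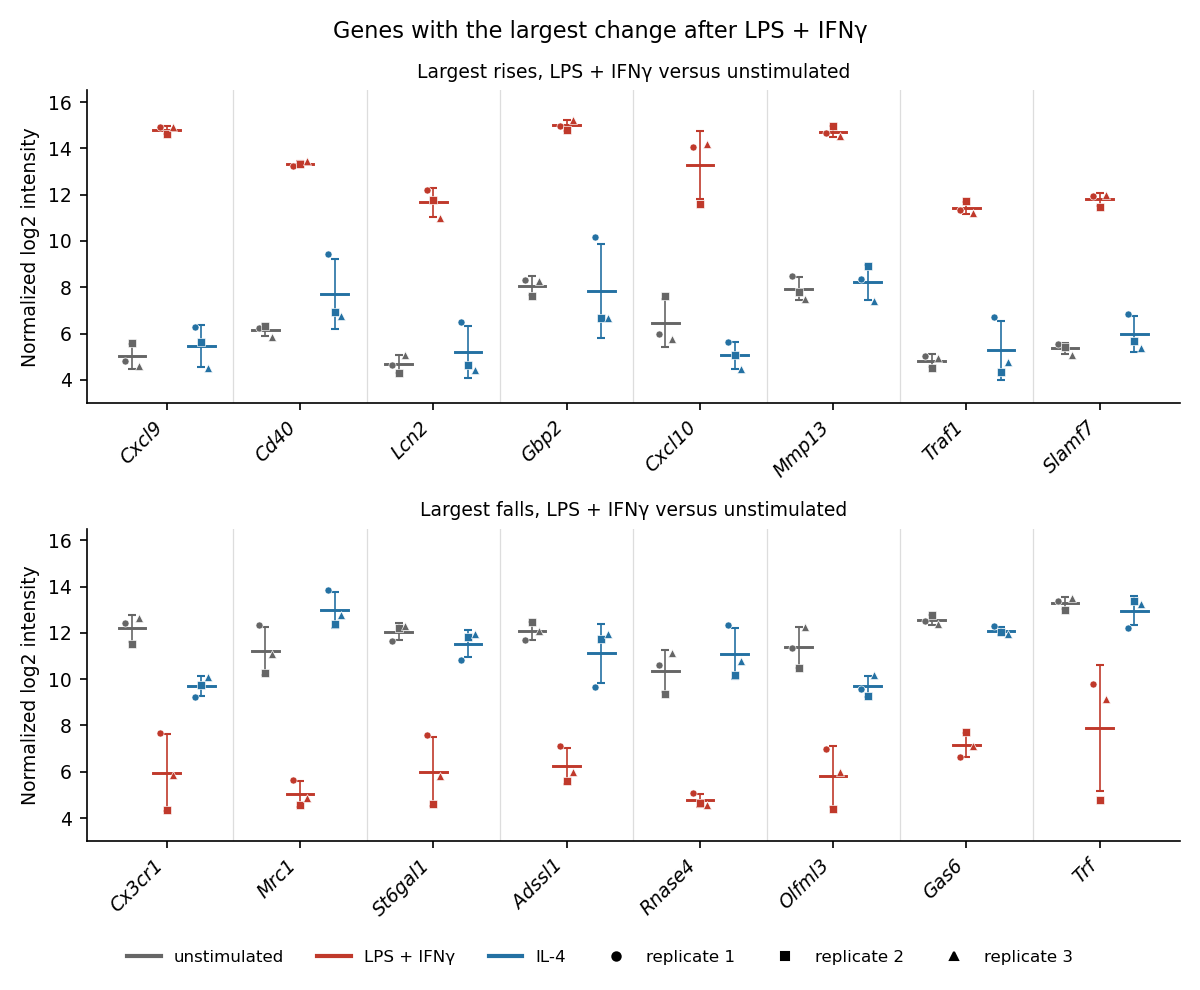
Normalized log2 intensity on each array (points, marker by replicate), with the mean and SD of 3 arrays (lines), for the 8 genes with the largest rise and the 8 with the largest fall after LPS + IFNγ that were detected in both groups. Cxcl9 rose by 9.80 and Cx3cr1 fell by 6.23 on the log2 scale.

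Cytokine and interferon genes rose together. Of 20 measured inflammatory cytokines and chemokines, 16 rose and 0 fell (20 rose when adjusted over the list alone). Tnf rose by 5.52 (log2), Il1a by 4.71, and Il27, not above background without stimulus, at least 20.3-fold. In camera this list was up at adjusted p = 1.97e-16, and at adjusted p = 0.0261 with an estimated correlation (0.278 with that correlation and without LPS + IFNγ replicate 2). The mean of the list on the 3 LPS + IFNγ arrays was 3.98, 3.96 and 3.99 above the unstimulated mean. Of 27 interferon-stimulated antiviral genes, 15 rose and 0 fell (22 rose adjusted over the list alone), among them Oasl1 by 5.95, Rsad2 by 5.32 and Isg20 by 3.66. The antiviral list was up at adjusted p = 5.21e-13, and at adjusted p = 0.258 with an estimated correlation. Of 14 interferon-gamma GTPases and regulators, 12 rose (13 adjusted over the list alone), among them Cd274, the ligand of the PD-1 receptor, by 4.67, Irf1 by 3.33 and Tgtp1 at least 15.4-fold; adjusted p = 3.71e-13, and adjusted p = 0.119 with an estimated correlation.

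Genes of antigen presentation rose as well, though not all of them. Of 18 genes of MHC class I antigen processing, 8 rose (9 adjusted over the list alone), among them the class I transactivator Nlrc5 by 3.43, the peptide transporter subunit Tap2 by 2.55 and the proteasome activator Psme1 by 1.69 (camera adjusted p = 3.94e-07, and adjusted p = 0.236 with an estimated correlation). Of 15 genes of MHC class II and costimulation, 8 rose (9 adjusted over the list alone), among them the class II chains H2-Eb1 by 5.61, H2-Ab1 by 5.51 and H2-Aa at least 24.6-fold (adjusted p = 1.19e-06, and adjusted p = 0.110 with an estimated correlation). Of 27 genes of Toll-like receptor and NF-kB signalling, 17 rose and 2 fell (17 and 3 adjusted over the list alone), with Nfkbiz higher by 3.86, Irak3, a negative regulator, by 2.65 and Tlr6 by 1.99 (adjusted p = 3.92e-09, and adjusted p = 0.110 with an estimated correlation). Of 18 genes of nitric oxide, oxidative burst and antioxidant defence, 5 rose and 1 fell (6 and 1 adjusted over the list alone). Slc7a2, an arginine transporter, rose by 5.91, Sod2, the mitochondrial superoxide dismutase, rose by 2.51, and Nos2, the inducible nitric oxide synthase, rose at least 20.8-fold (list adjusted p = 0.00267, and adjusted p = 0.110 with an estimated correlation).

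Genes of resting microglia fell. Of 21 homeostatic microglia genes, 11 fell and 0 rose (12 fell and 2 rose adjusted over the list alone), among them the lipid receptor Trem2, which fell by 4.32 ± 0.31, the transcription factor Mef2c, which fell by 3.46, Fcrls, which fell by 3.33, and the growth factor receptor Csf1r, which fell by 2.64. The list was down at adjusted p = 0.000456, and at adjusted p = 0.137 with an estimated correlation. Of 21 lysosomal genes, 9 fell and 1 rose (12 and 1 adjusted over the list alone); Hexa, a hexosaminidase subunit, fell by 3.04, the acid lipase Lipa fell by 2.93 and Gusb fell by 2.41 (adjusted p = 0.00275, and adjusted p = 0.236 with an estimated correlation). Of 25 Alzheimer-linked genes, 5 fell and 0 rose (7 fell adjusted over the list alone); besides Trem2 and Mef2c, Tyrobp, the signalling partner of Trem2, fell by 1.65 and the lipid phosphatase Inpp5d fell by 1.11 (list adjusted p = 0.136). Inpp5d did not pass with slide as a block (adjusted p = 0.0727) or without unstimulated replicate 1 (0.0503). Of 21 scavenger, Fc and phagocytic receptors, 3 rose and 8 fell (4 and 9 adjusted over the list alone), and this list went both ways: Timd4, a phosphatidylserine receptor, rose by 4.90 and the scavenger receptor Marco by 4.34 (list adjusted p = 0.247). In the IL-4 response list Mrc1 fell, Ch25h, a cholesterol hydroxylase, rose by 4.55, and 22 of 24 did not pass (1 rose and 1 fell adjusted over the list alone, list adjusted p = 0.690). The adjusted p of Ch25h was 0.0678 with slide as a block.

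Cnr2, the cannabinoid receptor the study is about, fell by 3.19 ± 0.24 after LPS + IFNγ (log2, SE, n = 3 arrays per group, adjusted p = 0.000137). It was detected on all 3 unstimulated arrays and on none of the LPS + IFNγ arrays, so the fall is at least 4.5-fold, and the gene's other probe fell too. The fall passed the test with slide as a block (adjusted p = 0.00246) and without LPS + IFNγ replicate 2 (adjusted p = 2.45e-05). Of 13 measured endocannabinoid genes, 2 rose and 5 fell (2 and 8 adjusted over the list alone, list adjusted p = 0.247). Gpr18, a lipid receptor, rose by 5.43 and Ptgs2, cyclooxygenase, rose at least 13.2-fold. Daglb, which makes 2-arachidonoylglycerol, fell by 4.82, Abhd12, which hydrolyses it, fell by 3.72, Abhd4, of anandamide synthesis, fell by 2.74, and the lipid carrier Fabp5 fell by 2.52. These 4 falls did not pass with slide as a block (adjusted p = 0.0542, 0.179, 0.108 and 0.113), and without LPS + IFNγ replicate 2 they passed, with log2 differences of -3.81, -2.71, -2.21 and -2.03. All 4 were undetected on that array, and with its value raised to the lowest detected one they stood at -3.86, -2.75, -1.80 and -1.53. Without unstimulated replicate 3 the adjusted p of Abhd12, Abhd4 and Fabp5 was 0.0730, 0.0548 and 0.0683. Without replicate 2 that of Abhd12 and Fabp5 was 0.0793 and 0.0543, and without replicate 1 that of Abhd12 was 0.0637. The other 6 genes did not pass: Pparg differed by -2.30 (adjusted p = 0.0501), Gde1 by -0.81, Abhd6 by -0.73, Trpv2 by -1.40, Mgll by 0.62 and Napepld by 0.53. Trpv2 differed by -0.35 when LPS + IFNγ replicate 2 was left out (adjusted p = 0.254), while Napepld, at 1.51, Pparg, at -3.11, and Gde1, at -0.96, passed (0.0253, 0.00794 and 0.00778).

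Of 15 glycolysis genes, 4 rose and 0 fell (5 rose adjusted over the list alone), among them the hexokinase Hk3 by 2.08, Tpi1 by 1.82 and the glucose transporter Slc2a1 by 1.63 (adjusted p = 0.00107, and adjusted p = 0.236 with an estimated correlation). With slide as a block their adjusted p was 0.0634, 0.0638 and 0.120. Within slide 2 Tpi1 stood at 1.01 and Slc2a1 at 0.99, and the latter had an adjusted p of 0.0501 without unstimulated replicate 2. Of 23 cell cycle genes, 8 fell and 0 rose (8 fell and 1 rose adjusted over the list alone), among them the spindle checkpoint kinase Bub1b, which fell by 2.05 (-1.09 with its undetected value raised), and the mitotic kinase Plk1, at least 1.69-fold lower (adjusted p = 0.0945 with slide as a block). The cell cycle list was down at adjusted p = 0.0194 and at adjusted p = 0.642 with an estimated correlation. Its adjusted p was 0.121 without background correction, 0.238 in the deposited log2 table, 0.0678 with slide as a block, 0.0718 without LPS + IFNγ replicate 1, 0.0525 without LPS + IFNγ replicate 3, 0.120 without unstimulated replicate 3, 0.0597 without IL-4 replicate 2 and 0.0505 without IL-4 replicate 3. Of 12 ribosomal protein genes, 5 fell and 0 rose (8 fell adjusted over the list alone), among them Rps19, which fell by 1.68, and Rpl10a, which fell by 1.16 (adjusted p = 0.000859, and adjusted p = 0.236 with an estimated correlation); with median centring the list's adjusted p was 0.314. With slide as a block the adjusted p of Rps19 was 0.106 and that of Rpl10a 0.0573. Of 18 cholesterol synthesis genes, 4 fell and 0 rose (8 fell adjusted over the list alone), among them Sqle, which fell by 2.58, and Dhcr7, which fell by 2.05, or -1.57 and -1.08 with the undetected values raised (list adjusted p = 0.0992, 0.0425 with slide as a block, 0.0257 without unstimulated replicate 2 and 0.0424 without replicate 3). The adjusted p of Sqle was 0.184 with slide as a block, 0.105, 0.0565 and 0.0649 without unstimulated replicate 1, 2 or 3, and 0.0502 without IL-4 replicate 3. Of 19 genes of oxidative phosphorylation, cytochrome c (Cycs) rose by 1.97, 18 did not pass and 1 rose adjusted over the list alone (list adjusted p = 0.261). Of 11 complement genes, the C1 inhibitor Serping1 rose at least 16.1-fold and 10 did not pass (1 rose adjusted over the list alone, list adjusted p = 0.30).

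Markers of astrocytes, neurons, endothelial, mural and fibroblast cells, and lymphocytes and neutrophils were mostly at background. Of the oligodendrocyte lineage markers 6 of 13, and of the border macrophage markers 6 of 8, were detected on at least 3 arrays. Of 14 astrocyte markers 5 were measured and 0 passed (0 adjusted over the list alone, list adjusted p = 0.915), and of 14 neuron markers 2 were measured and 0 passed (0 adjusted over the list alone, list adjusted p = 0.915). Of 14 endothelial, mural and fibroblast markers, 2 were measured and 0 passed (0 adjusted over the list alone, list adjusted p = 0.458). Of 6 measured markers of the oligodendrocyte lineage, Mbp, a myelin protein gene also transcribed in immune cells, fell by 2.54, and Cnp and Mag rose by 1.58 and 1.67 (2 rose and 1 fell adjusted over the list alone, list adjusted p = 0.361). With slide as a block the adjusted p was 0.0725 for Mbp, 0.185 for Cnp and 0.210 for Mag. Without LPS + IFNγ replicate 1 it was 0.0598, 0.0571 and 0.0565, without unstimulated replicate 2 it was 0.0660, 0.0962 and 0.0963, and without unstimulated replicate 3 it was 0.0659, 0.0904 and 0.0670. Mbp also missed the threshold without LPS + IFNγ replicate 3 (0.0567) or unstimulated replicate 1 (0.0703), and Mag without the latter (0.0507). Of 6 border macrophage markers only Mrc1 passed, lower after LPS + IFNγ (1 fell adjusted over the list alone, list adjusted p = 0.343). S100a8, the 1 measured gene among markers of lymphocytes and neutrophils, rose by 1.56 (1 adjusted over the list alone). Its adjusted p was 0.213 with slide as a block, 0.0757 without LPS + IFNγ replicate 1, 0.0763 and 0.0816 without unstimulated replicates 1 and 2, and 0.0523 without IL-4 replicate 2 or 3. Of 9 housekeeping genes, Pgk1 rose by 1.5, Gusb fell by 2.41 and 7 did not pass (1 rose and 1 fell adjusted over the list alone, list adjusted p = 0.769; Pgk1 at adjusted p = 0.0641 with slide as a block).

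The number of list members past the test depended on slide and on the weak array. In the fit with slide as a block, 9 cytokines and chemokines, 3 antiviral genes, 9 GTPases, 5 MHC class I genes, 4 MHC class II genes and 10 Toll-like receptor and NF-kB genes rose. In the same fit 6 homeostatic, 3 lysosomal, 3 Alzheimer-linked, 1 endocannabinoid (Cnr2), 1 cell cycle and 1 cholesterol gene fell. No glycolysis, ribosomal protein or oligodendrocyte gene passed there, while as lists glycolysis and ribosomal genes stood at adjusted p = 0.00283 and 0.00109 in camera. When LPS + IFNγ replicate 2 was left out, 23 antiviral, 14 MHC class I, 3 complement and 3 oxidative phosphorylation genes rose, and 8 Alzheimer-linked (2 others rose), 7 cholesterol (1 other rose) and 9 ribosomal genes fell.

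In total 2655 of 16895 probes changed in this comparison, 900 higher and 1755 lower. By gene, 575 of 9391 rose and 1143 fell. The median over all probes was -0.22 (log2) and moved to -0.83 with median centring, where 1390 probes changed, 2.16% of them higher; with cyclic loess it was -0.015, with 45% of the calls higher against 33.9%. Without LPS + IFNγ replicate 2, 5290 probes changed, 45.8% of them higher, and 2637 of the 2655 calls were among them with the same direction. Genes detected on the LPS + IFNγ arrays alone, such as Upp1, Gbp2b, Il27 and Nos2, then fall out of the test by construction. Without unstimulated replicate 1, 2 or 3, the count was 1598, 1656 and 1497. All unstimulated arrays sit on slide 2. With slide as a block 981 probes changed, 978 of them among the 2655, and all 2655 kept their direction. Within slide 2, 1 LPS + IFNγ array against 3 unstimulated arrays gave 3098 changed probes (the lone arrays are assumed to vary like the unstimulated ones); slide 1 holds no unstimulated array.

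IL-4 was compared with no stimulus to describe alternative activation. Arg1, arginase, the enzyme that turns arginine into ornithine, rose by 7.15 ± 0.73 (log2, SE, n = 3 arrays per group, adjusted p = 0.0169, limma), and both its probes passed. It was detected on 1 unstimulated array, and with the other 2 values raised to the lowest detected ones it rose by 6.84. Dusp4, a phosphatase of MAP kinases, rose by 3.46 ± 0.32 on 1 of its 3 probes and the transcription factor Egr2 by 3.07 ± 0.37. With replicate as a block on the 9 arrays their adjusted p was 0.0545 and 0.134, and that of Arg1 was 0.0338. Not above background in unstimulated cells, Retnla, a secreted protein of alternatively activated macrophages, rose at least 129-fold, Rnase2a, a ribonuclease of the eosinophil-associated family, at least 32.6-fold and the lectin Mgl2 at least 14.5-fold. A second probe of Mgl2, detected on 1 unstimulated array, rose by 2.74. These 6 genes rose out of 9391 and 0 fell. In addition a probe of Clic4, a chloride channel protein, rose by 1.53, and a probe without a gene name fell by 2.82, both named after their values were seen. Cnr2 differed by 0.39 ± 0.24 after IL-4 and did not pass (adjusted p = 1.00).

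**Figure D3:**
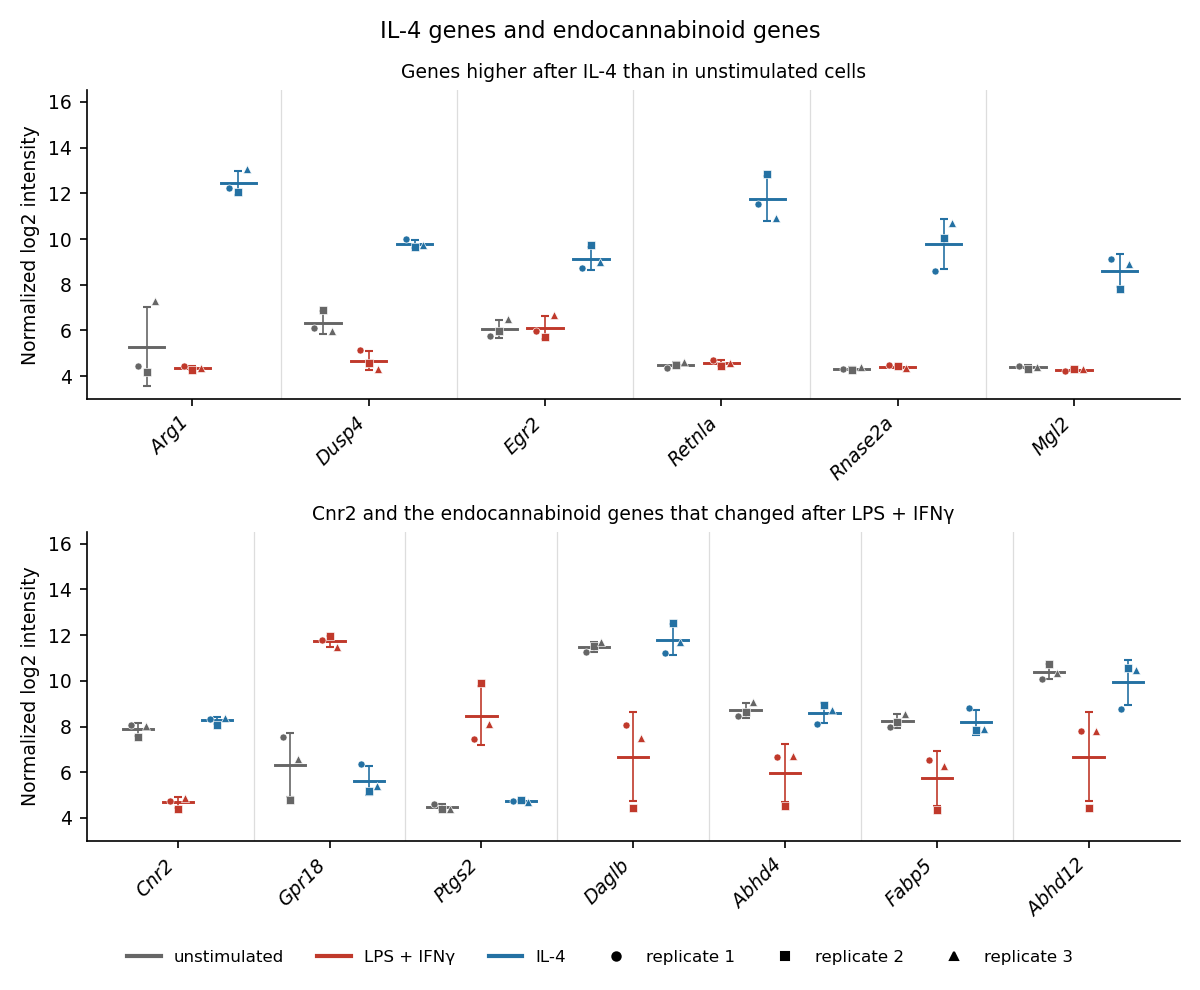
Normalized log2 intensity on each array (points, marker by replicate), with the mean and SD of 3 arrays (lines), for the 6 genes that rose after IL-4 (top) and for the endocannabinoid genes that changed after LPS + IFNγ (bottom). Cnr2 lies near 8 in unstimulated and IL-4 cells and was not detected on any LPS + IFNγ array.

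The IL-4 response list carried most of this change. Of its 24 measured genes, 5 rose and 0 fell, and 15 rose when adjusted over the list alone. It was up at adjusted p = 3.41e-33, and at adjusted p = 0.0093 with an estimated correlation (0.102 with that correlation and without LPS + IFNγ replicate 2). Its mean on the 3 IL-4 arrays was 2.52, 1.74 and 2.17 above the unstimulated mean. Mrc1 differed by 1.77 (adjusted p = 0.916).

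In all other lists 0 genes passed in limma, and set tests found small shifts. Homeostatic microglia genes were lower as a list (21 genes, 0 past the test and 0 adjusted over the list alone, median log2 difference -0.44, adjusted p = 5.63e-05, and adjusted p = 0.110 with an estimated correlation), with Cx3cr1 at -2.5 and P2ry13 at -2.28. Toll-like receptor and NF-kB genes were lower (27 genes, 0 past the test, 4 lower adjusted over the list alone, median -0.23, adjusted p = 0.000390, and adjusted p = 0.236 with an estimated correlation), with Tlr2 at -2.36 and Cd14, a co-receptor of LPS, at -2.06. Alzheimer-linked genes were lower (25 genes, 0 adjusted over the list alone, median -0.31, adjusted p = 0.00135, and adjusted p = 0.110 with an estimated correlation), with Cd33 at -1.92. Scavenger, Fc and phagocytic receptors were lower (21 genes, 1 adjusted over the list alone, median -0.31, adjusted p = 0.00205, and adjusted p = 0.110 with an estimated correlation). Genes of oxidative phosphorylation were higher (19 genes, 0 adjusted over the list alone, median 0.32, adjusted p = 6.77e-05, and adjusted p = 0.210 with an estimated correlation), with Ndufv1 at 0.55. With median centring 4 of these 5 lists did not pass, at adjusted p = 0.0677 for Toll-like receptor, 0.0708 for Alzheimer-linked, 0.158 for scavenger and 0.126 for oxidative phosphorylation genes.

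Interferon genes after IL-4 differed between replicates. On the IL-4 arrays the mean of the antiviral list stood at 1.72, -0.91 and -0.22 relative to unstimulated cells for replicates 1, 2 and 3, and that of the interferon-gamma GTPases at 1.41, -0.23 and -0.12. With all arrays the antiviral list did not pass (median 0.28, adjusted p = 0.272, and adjusted p = 0.847 with an estimated correlation). The GTPase list was up at adjusted p = 0.0153, and adjusted p = 0.623 with an estimated correlation (0 genes past the test, 1 adjusted over the list alone). Without IL-4 replicate 1, at the preset correlation, the antiviral list was down at adjusted p = 7.97e-10 and the GTPase list stood at adjusted p = 0.118 and down. The estimated correlation was not tried without that array. The GTPase list also did not pass without unstimulated replicate 2 (adjusted p = 0.188) or with slide as a block (0.811). With replicate as a block it stood at 0.0146 on the 9 arrays and at 0.120 on the 6 IL-4 and unstimulated arrays. The antiviral list was up without IL-4 replicate 2 (adjusted p = 1.51e-07), IL-4 replicate 3 (0.0150) or unstimulated replicate 1 (0.0386). IL-4 replicate 1 also had Gja1, an astrocyte and fibroblast connexin, at 10.7 against 4.38 and 5.14 on replicates 2 and 3, and Acta2, smooth muscle actin, at 11.1 against 5.49 and 6.51 (normalized log2). The list of 2 measured endothelial, mural and fibroblast genes, Acta2 and Pecam1, was up (0 past the test, 1 adjusted over the list alone, adjusted p = 0.0329, and adjusted p = 0.236 with an estimated correlation), and without IL-4 replicate 1 its adjusted p was 0.350, with slide as a block 0.222, without LPS + IFNγ replicate 2 0.102, and without unstimulated replicate 2 or 3 0.139 and 0.0502. The 2 measured neuron markers, Syn1 and Rbfox3, stood at 0.84 and 0.66 (0 adjusted over the list alone, adjusted p = 0.0139, and adjusted p = 0.236 with an estimated correlation), and without IL-4 replicate 1 their adjusted p was 0.131, with slide as a block 0.0964, without LPS + IFNγ replicate 2 0.0628 and without unstimulated replicate 2 0.0898.

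Other lists passed after IL-4 in some fits. Cytokines and chemokines (adjusted p = 0.272 with all arrays) were down with slide as a block (0.0241) and without IL-4 replicate 1 (0.00268). Cell cycle genes (0.190) were up with slide as a block (0.00928), without IL-4 replicate 1 (8.13e-05) and without unstimulated replicate 3 (0.00188), and ribosomal protein genes (0.0997) without the same arrays (0.0177 and 0.0396). MHC class I genes (0.138) were up without IL-4 replicate 2 (0.00561), IL-4 replicate 3 (0.0224) or unstimulated replicate 1 (0.0239), MHC class II genes (0.430) down without unstimulated replicate 2 (0.0257), border macrophage markers (0.469) up without unstimulated replicate 1 (0.00544) and glycolysis genes (0.274) down with slide as a block (0.0360).

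**Figure D4:**
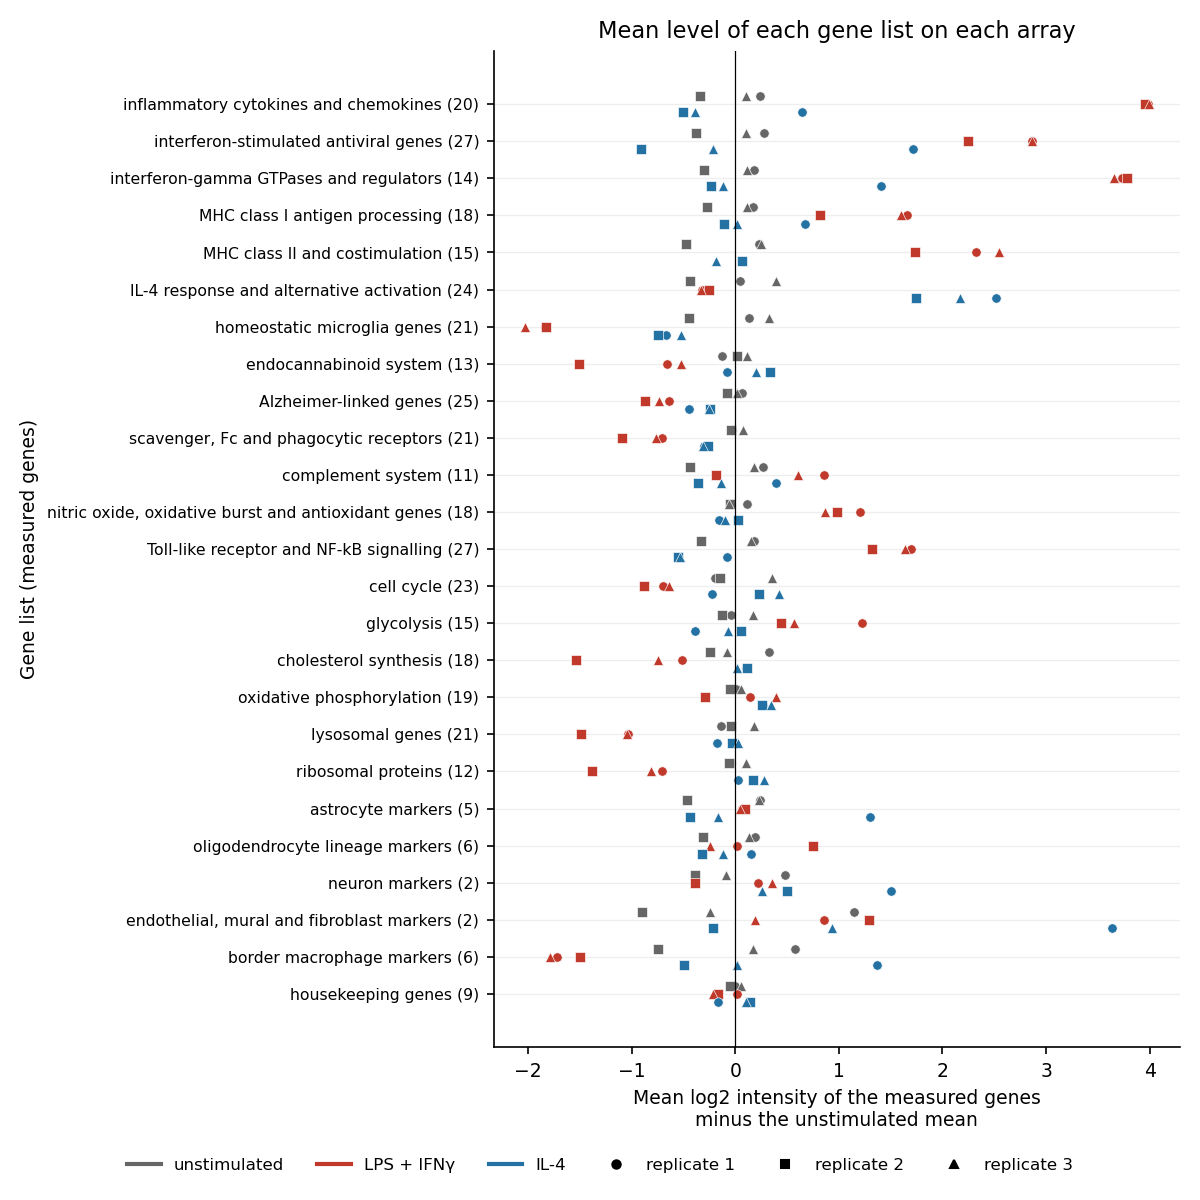
Mean log2 intensity of the measured genes of each list on each array, minus the unstimulated mean (points coloured by group, marker by replicate; number of measured genes in brackets). The IL-4 list stands at 2.52, 1.74 and 2.17 on the IL-4 arrays, and the antiviral list at 1.72 on IL-4 replicate 1 and at -0.91 and -0.22 on replicates 2 and 3.

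In total 10 of 16895 probes changed after IL-4, 9 higher and 1 lower, and 605 had an unadjusted p under 0.05. All 10 were among the 44 that changed without LPS + IFNγ replicate 2. With replicate as a block, 5 probes changed on the 9 arrays, and 104 without LPS + IFNγ replicate 2 or on the 6 IL-4 and unstimulated arrays alone. The labels do not say whether equal numbers pair these samples, and the block rests only on the correlations given above. The count was 0 without IL-4 replicate 1 (464 at an unadjusted p under 0.05, limma), 0 without IL-4 replicate 2 (495), 1 without IL-4 replicate 3, 3 and 5 without unstimulated replicates 1 and 3, and 5 without LPS + IFNγ replicate 1. With slide as a block 4 probes changed, and the adjusted p was 0.144 for Arg1, 0.141 for Dusp4 and 0.263 for Egr2, against 0.0203 for Retnla. Without IL-4 replicate 1, 2 or 3 the adjusted p of Arg1 was 0.206, 0.119 and 0.192, that of Dusp4 0.157, 0.0907 and 0.137 and that of Egr2 0.206, 0.182 and 0.237, while the probes of Retnla and Rnase2a and the brighter probe of Mgl2 were then detected on 2 arrays and not tested. Without unstimulated replicate 1 it was 0.120 for Arg1, 0.0984 for Dusp4, 0.289 for Egr2 and 0.0629 for Rnase2a. Dusp4 stood at 0.0634 without unstimulated replicate 3, Egr2 at 0.157 and 0.137 without unstimulated replicates 2 and 3, and Arg1 and Egr2 at 0.0554 and 0.120 without LPS + IFNγ replicate 1. Within slide 2, 1 IL-4 array against 3 unstimulated arrays gave 0 changed probes in limma (921 at an unadjusted p under 0.05).

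LPS + IFNγ was compared with IL-4 to set the stimuli against each other. They also differ in length, 16 h against 48 h. Cxcl9 was higher after LPS + IFNγ by 9.34 ± 0.46 (log2, SE, n = 3 arrays per group, adjusted p = 3.12e-05, limma), Cxcl10 by 8.22 ± 0.76, Cd69, an early activation marker, by 7.31 ± 0.53, Acod1, which makes itaconate, by 7.13 ± 0.66 and Tnf by 6.78 ± 0.40. Gbp2, Mmp13 and Lcn2 were higher by 7.15, 6.50 and 6.46. Among genes not above background after IL-4, Upp1 was at least 87.2-fold higher, Gbp2b at least 73.1-fold, the cytokine Il6 at least 38.9-fold and the chemokine Cxcl2 at least 32.3-fold. In the other direction Mrc1 fell by 7.96 ± 0.58, Rnase4 fell by 6.34 ± 0.60, Hfe, a regulator of iron uptake, fell by 5.55 ± 0.44 and Dusp4 fell by 5.11 ± 0.32. St6gal1 fell by 5.54, Daglb fell by 5.13, Trf fell by 5.05 (adjusted p = 0.0679 and 0.0683 without IL-4 replicate 2 or 3) and Mxd4, a repressor of the Myc network, fell by 5.03. Daglb fell by 4.11 and Trf fell by 3.47 when LPS + IFNγ replicate 2 was left out. None of these 8 genes was detected on all 3 LPS + IFNγ arrays, and with undetected values raised to the lowest detected ones Mrc1 fell by 7.02, Rnase4 fell by 5.32, Hfe fell by 4.48, Dusp4 fell by 3.99, St6gal1 fell by 4.63, Daglb fell by 4.16, Trf fell by 4.21 and Mxd4 fell by 4.03. Not above background after LPS + IFNγ, Arg1 was at least 107-fold lower, Retnla at least 66.9-fold, Slco2b1 at least 42.6-fold and Hpgd at least 35.3-fold. Cnr2 fell by 3.58 ± 0.24, at least 5.91-fold (adjusted p = 8.33e-05).

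Of 24 genes of the IL-4 response, 16 were lower after LPS + IFNγ than after IL-4 and 1 was higher (17 and 3 adjusted over the list alone), with Mgl2 at least 7.5-fold and Rnase2a at least 16.9-fold lower (list adjusted p = 2.33e-05, and adjusted p = 0.110 with an estimated correlation). Cytokines and chemokines were higher (15 of 20, 17 adjusted over the list alone, adjusted p = 4.24e-17, and adjusted p = 0.0261 with an estimated correlation, or 0.278 if LPS + IFNγ replicate 2 is also left out). Toll-like receptor and NF-kB genes were higher in 18 of 27 and lower in 1 (19 and 3 adjusted over the list alone, adjusted p = 3.98e-12, and adjusted p = 0.110 with an estimated correlation), with Nfkbiz at 5.17 and Irak3 at 3.64. Homeostatic genes were lower in 9 of 21 and higher in 2 (12 and 2 adjusted over the list alone, adjusted p = 0.0157, and adjusted p = 0.236 with an estimated correlation), with Trem2 lower by a log2 difference of -4.25; without LPS + IFNγ replicate 1 the list's adjusted p was 0.0575. Ribosomal protein genes were lower in 7 of 12 (12 adjusted over the list alone, adjusted p = 0.000124, adjusted p = 0.210 with an estimated correlation and 0.169 with median centring), and of these Rps2, at -0.92, moved to 0.025 with cyclic loess and had an adjusted p of 0.0560 and 0.0597 without IL-4 replicate 2 or 3. Glycolysis genes were higher in 4 of 15 (7 adjusted over the list alone, adjusted p = 9.94e-05, and adjusted p = 0.215 with an estimated correlation), with Slc2a1 at 2.13 and Pgk1 at 1.32, the latter at -0.0095 with median centring. Antiviral genes were higher in 11 of 27 (19 adjusted over the list alone, adjusted p = 1.58e-12, and adjusted p = 0.265 with an estimated correlation), the GTPases in 12 of 14 (12, 1.71e-12 and adjusted p = 0.128 with an estimated correlation), MHC class I genes in 8 of 18 (8, 1.53e-06 and adjusted p = 0.236 with an estimated correlation) and MHC class II genes in 9 of 15 (10, 1.28e-07 and adjusted p = 0.110 with an estimated correlation). Nitric oxide and oxidative burst genes were higher in 6 of 18 (7 higher and 1 lower adjusted over the list alone, adjusted p = 0.000859, and adjusted p = 0.110 with an estimated correlation). Cell cycle genes were lower in 8 of 23 (12 adjusted over the list alone, adjusted p = 0.00493, adjusted p = 0.579 with an estimated correlation and 0.0505 without IL-4 replicate 3), and lysosomal genes in 10 of 21 (13 adjusted over the list alone, adjusted p = 0.00275, adjusted p = 0.236 with an estimated correlation and 0.0525 with median centring). Cholesterol synthesis genes were lower in 5 of 18 (8 adjusted over the list alone) and as a list did not pass (adjusted p = 0.0661, and adjusted p = 0.623 with an estimated correlation). That list passed with a replicate block (0.0365), median centring (0.0352) and cyclic loess (0.00677), and without LPS + IFNγ replicate 2 (0.0348), IL-4 replicate 3 (0.0436) or unstimulated replicate 1, 2 or 3 (0.0240, 0.0323 and 0.0290). It also passed with both blocks (0.03), within slide 1 (0.0129), with the mean of all kept probes (0.0107) and with no filter on dim probes (0.000882). When LPS + IFNγ replicate 2 was left out, 21 antiviral and 8 glycolysis genes were higher, and 13 cell cycle genes (3 others higher) and 8 cholesterol genes lower. Within slide 1 the IL-4 response list stood at adjusted p = 0.0835 and the cell cycle list at 0.143.

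In this comparison 2463 probes differed, 818 higher and 1645 lower after LPS + IFNγ. By gene, 534 were higher and 1093 lower. The share of higher probes among the calls depended on the scaling. It was 33.2% here, 49.3% with cyclic loess, 2.8% with median centring and 45.3% without LPS + IFNγ replicate 2. Without LPS + IFNγ replicate 2 the count was 4980 and held 2449 of the 2463, without IL-4 replicate 2 it was 1334 and without IL-4 replicate 3 it was 1190. With slide as a block 2075 probes differed. Within slide 1, 2 arrays against 2, of which 1 is the weak array, gave 0 in limma (1261 at an unadjusted p under 0.05), so none of the genes above passed there. Slide 2 holds 1 array of each of these groups.

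Across the 3 groups 2416 probes differed in the F-test, 4995 without LPS + IFNγ replicate 2, 1543 without IL-4 replicate 3, 1561 without unstimulated replicate 3 and 1514 with slide as a block. Probes changed by both stimuli were few. A probe of Clic4 rose after LPS + IFNγ (1.93, log2) and after IL-4 (1.53). The brighter probe that stands for Clic4 did not pass after IL-4. A probe of Dusp4 fell by 1.66 after LPS + IFNγ and rose by 3.46 after IL-4. Both were named after their values were seen. This Dusp4 probe was detected on 1 LPS + IFNγ array, and with the other 2 values raised to the lowest detected ones the difference was -0.54. Without LPS + IFNγ replicate 2 it stood at -1.795 after LPS + IFNγ. Other Dusp4 probes then stood at -0.821 and 0.1237 and did not pass (adjusted p = 0.173 and 0.821, limma). Independent lists of these sizes would share 0.479 probes higher and 0.988 in opposite directions. Both comparisons use the same 3 unstimulated arrays, which cannot be split into parts of 2. Across all probes their log2 differences had a covariance of 0.094, against 0.029 to 0.040 in 100 simulations with no effect, and a correlation of 0.225, against 0.177 to 0.237. The simulations held no slide difference. Since all unstimulated arrays are on slide 2, such a difference would enter both comparisons, so the covariance does not show a shared response. Without LPS + IFNγ replicate 2, 17 probes changed in the same direction in both comparisons, and 0 without any 1 of the IL-4 arrays, LPS + IFNγ replicate 1 or 3, or unstimulated replicate 1 or 3. In all 3 comparisons 34 of 75 list tests passed with the preset correlation and 3 with the estimated correlation, those of cytokines and chemokines in both LPS + IFNγ comparisons and of the IL-4 list after IL-4. With the estimated correlation and without LPS + IFNγ replicate 2 these 3 stood at 0.278, 0.278 and 0.102 and did not pass. With the preset correlation at least 34 list tests passed in 5 of 100 drawn groupings of the 9 arrays, the real one included. The others of these groupings kept LPS + IFNγ replicates 1 and 2 together, so they are not free of a stimulus difference.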

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

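The fits that leave out LPS + IFNγ replicate 2 together with a slide block, a replicate block or IL-4 replicate 1, and the replicate block on 6 arrays, were chosen after the results were seen. For LPS + IFNγ against unstimulated cells (2655 probes) the count was 1390 with median centring, 981 with slide as a block, 0 with slide and replicate blocks (1862 at an unadjusted p under 0.05, limma), 1755 on the comparison's own 6 arrays and 6165 with array weights. It was 5290 without LPS + IFNγ replicate 2, 5424 with a replicate block too and 5967 without IL-4 replicate 1 too, and 1598, 1656 and 1497 without unstimulated replicate 1, 2 or 3. The cause of these changes was not tested except as given below.

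For IL-4 against unstimulated cells (10 probes) the count was 16 with cyclic loess, 5 with median centring, 26 in the deposited log2 table, 4 with slide as a block, 0 within slide 2, 5 with a replicate block, 0 with both blocks (195 at an unadjusted p under 0.05, limma), 19 on its own 6 arrays, 18 with trend and robust and 387 with array weights. Leaving out 1 array gave between 0 and 44: 0 without IL-4 replicate 1 or 2, 1 without IL-4 replicate 3, 5 without LPS + IFNγ replicate 1, 44 without its replicate 2, and 3 and 5 without unstimulated replicates 1 and 3. Without LPS + IFNγ replicate 2 it was 6 with slide as a block, 104 with a replicate block and 45 without IL-4 replicate 1, and on the 6 arrays with a replicate block 104.

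For LPS + IFNγ against IL-4 (2463 probes) the count was 1321 with median centring, 0 within slide 1, 1052 with both blocks, 1312 on its own 6 arrays, 6272 with array weights, 1334 and 1190 without IL-4 replicate 2 or 3, and 4980 without LPS + IFNγ replicate 2 (4448 with slide as a block, 5100 with a replicate block, 5250 without IL-4 replicate 1). The F-test (2416 probes) gave 1137 with median centring, 1514 with slide as a block, 417 with both blocks, 6365 with array weights, 1543 without IL-4 replicate 3, 1561 without unstimulated replicate 3, and 4995 without LPS + IFNγ replicate 2 (4036, 5084 and 5614 in the same 3 fits).

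Probes changed in the same direction by both stimuli (1) numbered 4 without background correction, 3 with the larger offset, 4 with cyclic loess, 0 with median centring, 9 in the deposited table, 0 with slide as a fixed block, 2 with it as a random block, 0 within slide 2, 0 with a replicate block or both blocks, 4 on own arrays, 3 with trend and robust, 165 with array weights, 17 without LPS + IFNγ replicate 2 (48 with a replicate block, 17 without IL-4 replicate 1) and 0 without any 1 of the arrays named in the report.

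Of the 75 list tests 34 passed, and 3 with the estimated correlation; those 3 did not pass with that correlation and without LPS + IFNγ replicate 2 (0.278, 0.278 and 0.102). List calls also ended in other planned fits, beside those given in the report. For LPS + IFNγ against unstimulated cells these were the cell cycle list without background correction (0.121) and in the deposited log2 table (0.238), the ribosomal list with cyclic loess (0.0958) and the glycolysis list within slide 2 (0.0603). After IL-4 they were the GTPase list in the deposited table (0.793) and with cyclic loess (0.0900) and, chosen after the results were seen, with a replicate block on the 6 arrays (0.120), and the neuron and the endothelial, mural and fibroblast markers without background correction (0.0675 and 0.0513), in the deposited table (0.219 and 0.317), with no filter on dim probes (0.210 and 0.0895) and within slide 2 (0.413 and 0.153), and the neuron markers with both blocks (0.0633). In LPS + IFNγ against IL-4 they were the IL-4 response (0.0835) and cell cycle lists (0.143) within slide 1. After IL-4 the antiviral list stood at adjusted p = 0.95 without unstimulated replicate 2 and turned down within slide 2 (0.0241), without IL-4 replicate 1 (7.97e-10) and without that array and LPS + IFNγ replicate 2 (1.84e-07), and the GTPase list in the same fits (0.283, 0.118 and 0.337) and with both blocks (0.945), with 4.93e-05 and up without IL-4 replicate 2 and 0.188 without unstimulated replicate 2. In LPS + IFNγ against IL-4, Pgk1 turned to -0.0095 with median centring and Rps2 to 0.025 with cyclic loess.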

Other observations

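With replicate as a block and LPS + IFNγ replicate 2 left out, a fit chosen after the results were seen, IL-4 changed 104 probes against unstimulated cells, with 52 genes higher and 27 lower. Beside Arg1 and Retnla, it raised the eosinophil chemokine Ccl24 by 3.79 (log2, n = 3 arrays per group), the arginine transporter Slc7a2 by 3.59, the aminopeptidase Anpep by 2.87, the amino acid oxidase Il4i1 by 2.48, the adhesion molecule Pecam1 by 2.43, the PD-1 ligand Cd274 by 2.11, the transferrin receptor Tfrc by 2.09, the liver X receptor Nr1h3 by 1.90, Mrc1 by 1.73 and the lipid-sensing receptor Pparg by 1.61. The genes named here were picked after their values were seen. Some with larger rises than Il4i1 were passed over, among them Gask1b (3.185), Cd74 (2.977) and St7 (2.835). Among the 27 lower genes, the fatty acid receptor Gpr84 fell by 2.77, the formyl peptide receptor Fpr2 fell by 2.76, the lectins Clec4n and Clec4e fell by 2.67 and 2.24, the purine receptor P2ry13 fell by 2.45, Tlr2 fell by 2.34 and Cd33, a sialic acid receptor linked to Alzheimer's disease, fell by 2.12. This block also covered LPS + IFNγ replicates 1 and 3. Their correlations with the unstimulated arrays of equal number, -0.0053 and -0.033, gave no ground for pairing. The same block on the 6 IL-4 and unstimulated arrays alone also gave 104 probes. The 2 fits shared 81 probes, but they use the same 6 arrays and the same block, so the overlap adds no support. All 3 pairs had the same direction for these probes, which the paired test selects for. The 10 calls of all 9 arrays were among the first 104. Slide as a block in place of replicate, without the same array, left 6 probes, and both blocks on all 9 arrays left 0 (limma, 195 at an unadjusted p under 0.05).

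The tests of the weak array and of IL-4 replicate 1, and that of the weak array as source of lost calls, were chosen after the results were seen; those of the slide as the whole source, of the deposited shift and of other splits were chosen before. LPS + IFNγ replicate 2 had 6208 detected probes. A wrong label is argued against, since its mean correlation with its own group exceeded the highest with another group by 0.054. An even loss of signal stays open. The spread of its difference from replicates 1 and 3 over 8445 bright probes was 4.25 times that between those 2 arrays. On the weak array 31.6% of the kept probes were detected, and an even loss that leaves probes in background could give such a spread too. An uneven loss of transcripts before hybridisation stays open too. For 1540 genes with 2 bright probes the deviations of the 2 correlated at 0.146, above the highest of 1000 shuffled pairings (0.0742). For the difference between replicates 1 and 3 the same correlation was higher, at 0.544, so the value does not single out a loss of transcripts. Most of the deviation was not shared between probes of a gene. No biological explanation was tested.

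The calls of LPS + IFNγ against unstimulated cells fell from 2655 to 981 with slide as a block. Within slide 2 the log2 differences of the 2655 probes were 0.95 times the full ones (median, quartiles 0.812 and 1.05), and 100% had the same sign. A call requires the LPS + IFNγ arrays to agree, so this ratio was nearly fixed by the choice of probes and cannot decide on slide. The 981 calls left with slide as a block argue against a slide difference as the whole source. The weak array may be a source of the lost calls, as without it the block left 0.724 of the calls, against 0.369 with it. Among the 1677 lost calls the median absolute log2 difference went from 1.37 to 1.26 and the median SE from 0.313 to 0.389. The same array may carry noise into the shift in the deposited log2 values, since the spread of the slide coefficient was 1.58 times as large with it. This spread was taken over the kept probes after background correction, and the deposited shift follows from signals without that correction.

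IL-4 replicate 1 had 110 probes at least 2 log2 units above both other IL-4 arrays, among them Ccl8 (13.02 against 5.87 and 6.50), Gja1 and Acta2, and 21 below. Astrocytes stay open: the other astrocyte markers were higher by a median of 0.129, but 6 of 14 were detected on no array, and the 4 others detected on at least 3 arrays were higher by a median of 0.712. Fibroblasts, mural or endothelial cells cannot be told apart from a state of the cells. Their markers other than Acta2 and Col1a1 were higher by a median of 0.185, and the 1 detected on at least 3 arrays, Pecam1, by 1.52. Col1a1 stood at 7.93 against 4.38 and 4.35, and Col1a2, Col3a1 and Dcn were near background at 4.86, 5.03 and 5.13. Ccn2, Serpinh1, Lox and Timp1 were among the 110. Border macrophage markers were higher by a median of 1.28, with 5 of 8 higher by more than 1 and F13a1 at -0.304. Whether border macrophages were in the culture was not tested. A culture shared with unstimulated replicate 1 could play a part, with a slope of 0.254 between the deviations of the 2 arrays, which leaves it open. Whether the interferon genes of this array reflect biology was not tested.

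Other splits of the 6 arrays, 10 per comparison, are too few for a share under 0.05. The real splits, 1 of 10 each, gave 2655, 10 and 2463 calls, and the highest others 0, 2 and 5; for IL-4, the other splits that part all 3 pairs gave 0. For the F-test, 1 of 100 drawn splits (280 are possible), the real one, gave as many as 2416 probes. The highest other gave 1884 by keeping the LPS + IFNγ arrays together while mixing IL-4 with unstimulated arrays. The count thus mostly reflects the LPS + IFNγ arrays standing apart, and the share does not show a difference among all 3 groups. For probes shared by both stimuli 3 of 100 splits gave at least the real 1, with 5 and 6 in the other 2. Nearly all other splits gave no call in the F-test either, so this share says little about 1 shared probe. For the list tests 5 of 100 gave at least the real 34, with 37 as the highest other. The other splits with at least 34 kept LPS + IFNγ replicates 1 and 2 together, so they still held a stimulus difference. This share therefore cannot decide whether chance gave the number of list calls.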
